A study of Saccharomyces cerevisiae SK1 with 28 samples.

How the data were processed

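The series holds ChIP-seq of wild-type SK1 budding yeast, a laboratory strain that sporulates efficiently. The labels name 7 states, each with 2 ChIP libraries and 2 input libraries, 28 libraries in all. The states were exponential growth in rich medium (vegetative), the same cells treated with DTT, 6 h and 21 h in BYTA, the medium that precedes sporulation, and 5.5 h, 6 h 45 min and 8 h in sporulation medium. Cells were grown at 30 °C and fixed with 1% formaldehyde for 15 min, per the labels' protocols. The protein that was immunoprecipitated, and the dose and duration of DTT, are not given in the sources used here.

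Each of the 14 ChIP libraries had 1 deposited table, and the 14 input libraries were not analysed here as tables of their own. Each row of a table pairs 1 peak summit with 1 promoter window and its gene, per the file headers. Bowtie2 2.3.4.1, SAMtools 1.7, MACS2 2.2.9.1 and ChIPseeker 1.44.0 are named in the submitters' processing notes, without the role of each. The SK1 assembly, the control used for each peak call and the read depth are not given in the sources used here. Tables were assigned to libraries by the library name inside the deposited peak names, and each table held peaks of 1 library, so peaks had been called per library. The deposited score of a summit is the authors' own value, and the file headers do not name its type. It was used only to rank or filter summits within a list. Peak numbers of the listed summits ran to between 1119 and 3099, while a table listed between 4 and 296 summits. The rule that selected the listed summits is not given in the sources used here, so a gene without a listed summit was not listed, which does not show that it was unbound. The lowest listed score differed between libraries, from 247 to 401.

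The promoter windows were 600 bp wide. For 310 listed summits between divergent genes, the reach of the windows upstream was worked out from the distance between the 2 gene starts in R64. Its median was 600 bp, with 281 of them within 5 bp of that and 166 at exactly 600 bp. A gene pair listed in several libraries counts once per library. All listed summits lay in such a window, so a test of the share of peaks in promoters had no content and was left out. Coordinates are those of the deposited SK1 tables. Gene names came from the tables, and all 551 systematic names matched the RefSeq gene table of the R64 reference assembly. Another 10 gene identifiers with no systematic name were left out of gene counts and tests.

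A gene was called in a state when both of its libraries listed a summit in its window. A summit in the windows of 2 divergent genes counted for both. Overlaps between states, and between a state and a gene list, were tested with one-sided exact hypergeometric tests against 6021 protein-coding genes. Benjamini-Hochberg adjustment was made within each family of comparisons, and over 112 tests for 16 lists in 7 states. Another list, of tRNA genes, was not tested because 0 tRNA genes were listed. Lists were compared between states with two-sided Fisher exact tests on genes called in one state and listed in no library of the other. This was done where both sets held at least 10 genes, and for DTT against 8 h in sporulation medium whatever their size. The threshold was an adjusted p of 0.05. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. With 2 libraries against 2, a two-sided permutation test of gene numbers cannot go below 0.333, so gene numbers per library are given without a test. Nothing says that the replicates came from separate cultures, so the spread between them may be technical. Overlap tests treat genes as independent, which neighbouring genes that share a summit are not.

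States, lists, tests and the rule for named genes were fixed before the data were examined. The plan named all annotated genes as the background, and the 6021 protein-coding genes were used instead. Named genes are the 10 best called genes of each state by mean within-list rank, and up to 4 members of each list past the threshold. To these were added the 5 best genes called in one state and listed in no library of another. HAC1 and KAR2 are given in every library. Other genes named below, including full memberships of lists and of small overlaps, were chosen after their values were seen. Alternatives were calling a gene in either replicate, each replicate alone, adjustment within 1 state and, for gene lists and overlaps with DTT, a background of the 551 listed genes. That background is made from these same lists, with 378 of its genes listed with DTT and 346 at 6 h in BYTA. A gene set of these states can exceed expectation there only by little, so a lost call is weak evidence against it. The replicate number as a block was tried as well. Chosen after the data were seen were counting a summit only for the nearest gene, keeping only scores of at least 500, the listed-gene background for the remaining overlaps, and list differences on genes listed per library.

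The scripts for overlaps and lists were tested on simulated data, with 100 random gene sets per state of the size called. Random sets called any list in 0 to 3% of draws and an overlap in 0 to 5%. A list with 5 members added to each set was recovered in 100% of draws in each of the 7 states. Sets held 7 to 282 genes, so 5 added members made recovery nearly certain, and power for fewer members was not measured. Random genes were drawn without the divergent pairs that share a summit. Adjustment in the simulation was within 1 state, not over the 112 tests of the results. These rates therefore check the scripts and are not the error rates or power of the reported tests. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The planned motif test needed the SK1 genome sequence, which was not used here.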

Results

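Promoter binding was profiled by ChIP-seq in SK1 yeast during growth, under DTT, before sporulation and during sporulation, with 2 ChIP libraries per state. DTT is a reducing agent that impairs disulfide bond formation and thereby protein folding in the endoplasmic reticulum (ER), which triggers the unfolded protein response (UPR). The 14 tables together listed 1055 summits, which made 1369 pairs of a summit and a promoter window, and 551 genes with a systematic name. The design asks which promoters are occupied in premeiotic and meiotic cells, and how these compare with those occupied when folding is disturbed from outside. Read depth is unknown from these tables.

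DTT-treated cells had the longest lists, with a mean of 330 ± 42.4 genes per library (SD, n = 2). Cells at 6 h in BYTA followed with 225.5 ± 162 genes (SD, n = 2), made of 340 genes in replicate 1 and 111 in replicate 2. The other 5 states had short lists. Vegetative libraries listed 20 ± 4.24 genes and libraries at 21 h in BYTA listed 36.5 ± 0.707 (SD, n = 2 each). In sporulation medium the means were 18 ± 15.6 at 5.5 h, 20 ± 5.66 at 6 h 45 min and 24 ± 7.07 at 8 h (SD, n = 2 each).

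**Figure D1:**
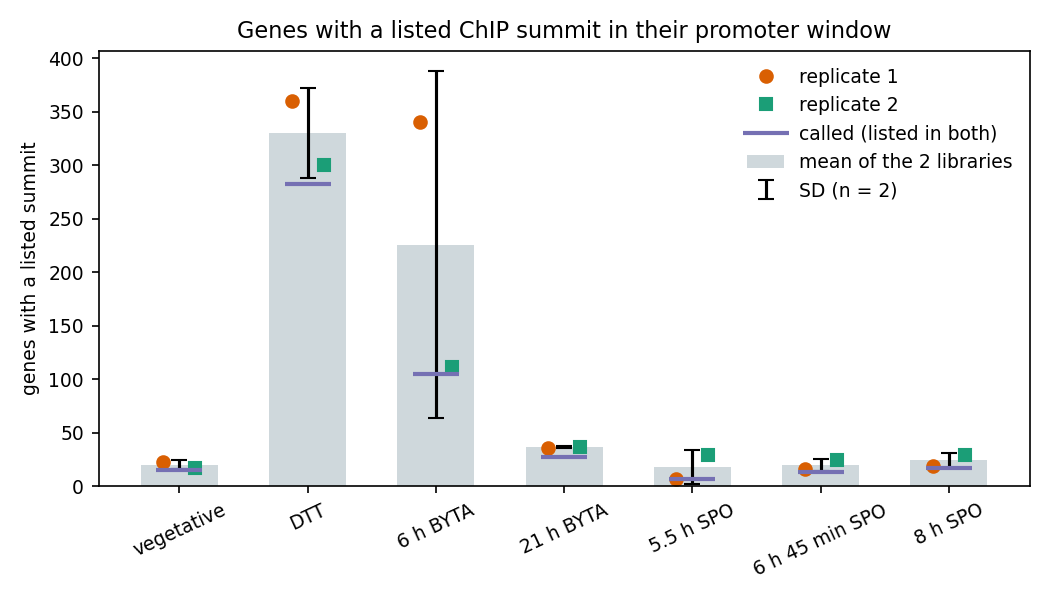
Number of genes with a listed summit in their promoter window, by state. Bars are means of 2 libraries with the SD, points are single libraries, purple dashes are genes listed in both, and SPO stands for sporulation medium. The DTT libraries list 360 and 300 genes, and those at 6 h in BYTA 340 and 111.

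Genes called in both replicates numbered 15 in vegetative cells, 282 with DTT, 105 at 6 h in BYTA and 27 at 21 h. They numbered 7, 13 and 17 at 5.5 h, 6 h 45 min and 8 h in sporulation medium. Replicates shared between 75% and 100% of the shorter list, more than chance gives in each state (one-sided exact hypergeometric tests, largest adjusted p = 2.75e-17). The median distance between replicate summits was 2 to 13 bp. At 6 h in BYTA the called genes are limited by replicate 2, and replicate 1 alone gave 340 genes. At 5.5 h in sporulation medium they are limited by replicate 1, which listed 4 summits, and replicate 2 alone gave 29 genes.

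KAR2, which encodes the ER Hsp70 chaperone BiP and is the classical target gene of the UPR, was listed in 11 libraries, more than any other gene. Its window spans positions 391422 to 392021 of chromosome X, immediately upstream of the gene (SK1_10G01690). Both vegetative, both DTT and both 6 h BYTA libraries listed it. It was also listed in 1 of the 2 libraries at 21 h in BYTA, in neither at 5.5 h in sporulation medium, and in both at 6 h 45 min and at 8 h. In the 9 libraries outside DTT its summit lay between positions 391854 and 391866, which is 156 to 168 bp upstream of the gene start. In the DTT libraries the summits lay 510 and 390 bp upstream, at positions 391512 and 391632. TAD2, the divergent neighbour that encodes a tRNA deaminase subunit, has a window from 391697 to 392296. The DTT summits lie outside it, so TAD2 was listed in 9 libraries and in neither DTT library.

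**Figure D2:**
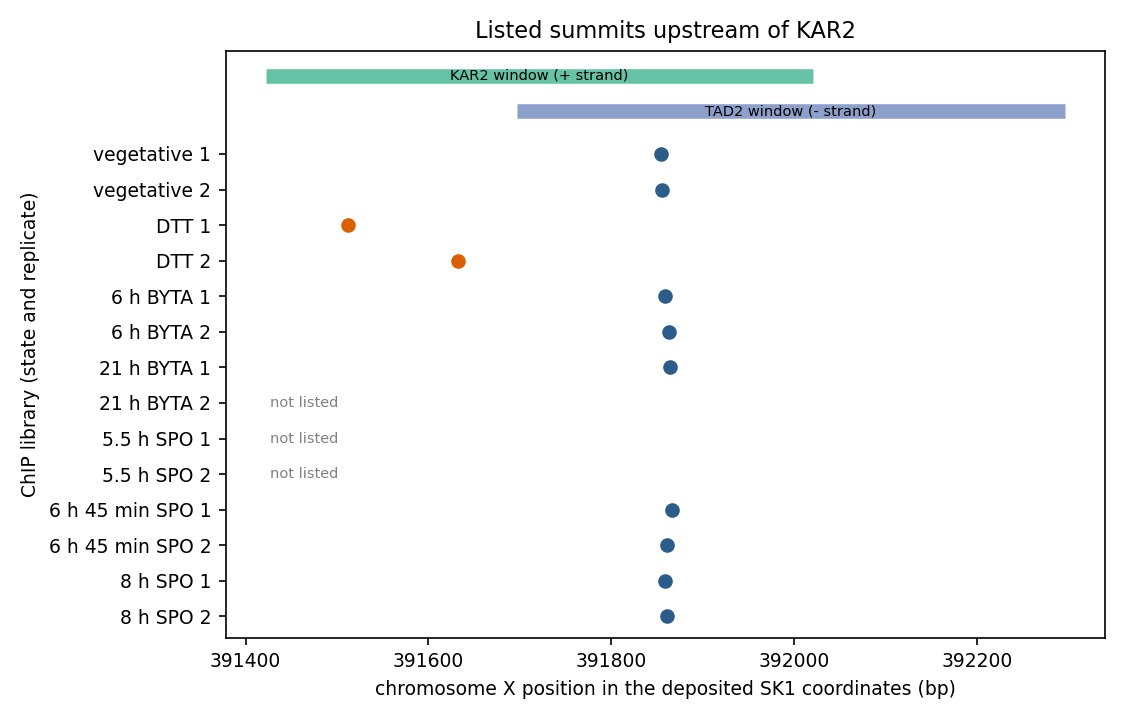
Position of the listed summit upstream of KAR2 on chromosome X in each of 14 ChIP libraries, with the promoter windows of KAR2 and TAD2 drawn as bars. Points are summits, orange for DTT, and SPO stands for sporulation medium. The 9 summits outside DTT lie between 391854 and 391866 and those with DTT at 391512 and 391632.

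HAC1, which encodes the UPR transcription factor, had a listed summit in its own promoter in both DTT libraries and both libraries at 6 h in BYTA. The summits lay 221 to 229 bp upstream of the gene (SK1_06G00360, window 95498 to 96097 of chromosome VI). The library of replicate 1 at 6 h 45 min in sporulation medium also listed HAC1, 226 bp upstream, and the other 9 libraries did not.

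In vegetative cells the best-ranked called gene was PSA1, which encodes GDP-mannose pyrophosphorylase, an enzyme of glycosylation. KAR2 with TAD2, DFR1, FSF1 with YTM1, UTR5, MRPS17 with GCV2, and TRS31 completed the first 10. Of the 19 genes of the ER protein folding list, KAR2 and PDI1, the latter encoding protein disulfide isomerase, were called. This is 42.3 times the number expected by chance (one-sided exact hypergeometric test, adjusted p = 0.0217, 2 of 2 libraries each). KAR2 shares its vegetative summits with TAD2, whose start lies nearer, and the list's call ended when each summit counted only for the nearest gene (exact test, adjusted p = 0.383). It also ended with scores of at least 500 (exact test, adjusted p = 0.464) and against the 551 listed genes alone (adjusted p = 1).

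DTT treatment went with a list of 282 called genes, of which 272 were listed in neither vegetative library. The best-ranked were ICT1 with ERG27, IRC4, GLK1 with PDI1, ERO1, PBI2, TSA1, APQ12 and ROX1. GLK1 encodes glucokinase. ERO1 encodes the ER thiol oxidase that recharges Pdi1, TSA1 a thioredoxin peroxidase, ERG27 an enzyme of ergosterol synthesis and ROX1 a repressor of hypoxic genes. ICT1, ERG27, IRC4, ERO1 and PBI2 led the genes called with DTT and listed in no vegetative library. Of the 15 vegetative genes, 8 were also called with DTT, namely DFR1, FSF1, GLK1, KAR2, PDI1, PSA1, TAL1 and YTM1, against 0.703 expected by chance (adjusted p = 2.03e-07, one-sided exact hypergeometric test). Against the 551 listed genes alone this overlap did not pass (exact test, adjusted p = 0.537). Mean summits of 6 of these 8 genes lay within 100 bp between the states, KAR2 and TAL1 being the exceptions. The 5 vegetative genes listed in no DTT library were TAD2, UTR5, MRPS17, GCV2 and YDR042C.

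Genes for protein folding in the ER were over-represented with DTT, with 9 of 19 called, 10.1 times the number expected by chance (one-sided exact hypergeometric test, adjusted p = 6.54e-06). They were the chaperone gene KAR2, the genes of its nucleotide exchange factors LHS1 and SIL1 and of its J-domain partners JEM1 and ERJ5, and the oxidative folding genes PDI1, EUG1, MPD1 and ERO1. Their summits lay 36 to 38 bp upstream of ERJ5, 87 and 95 bp upstream of SIL1, 136 and 140 bp upstream of ERO1, and 150 and 152 bp upstream of EUG1. SCJ1, another ER J-domain gene, was listed in 1 DTT library. The list of glycolysis and other strongly transcribed genes also passed, with 7 of 20 called (7.47 times expectation, exact test, adjusted p = 5.89e-04). Its called members were PGK1, CCW12, CDC19, FBA1, HXT3, PDC1 and PGI1, which include glycolytic enzyme genes, a cell wall protein gene and a glucose transporter gene.

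The other lists did not pass with DTT. Cytosolic heat shock had 4 of 20 called, BTN2, SSA1, SSA2 and UBI4 (exact test, adjusted p = 0.201), and acetate and glyoxylate metabolism 3 of 17, MDH2, MLS1 and PCK1 (adjusted p = 0.439). Glycosylation and GPI anchors had 5 of 48, among them PMT1 and PMT2 for protein mannosylation (exact test, adjusted p = 0.516), and amino acid synthesis 3 of 24, HIS1, HOM3 and LYS20 (adjusted p = 0.620). For translocation into the ER, 2 of 21 were called, the translocon genes SEC61 and SEC62. ER to Golgi vesicle traffic had 2 of 34, ER shape and phospholipid synthesis 2 of 29 with INO2 and SCS3, translation factors 2 of 34, and general stress 2 of 19. UPR signalling had 1 of 4, HAC1, and middle meiosis and spore wall 1 of 32, CRR1. ER-associated degradation had 0 of 16 called, with DER1 and SSM4 each listed in 1 DTT library, early meiosis 0 of 23, and ribosomal proteins 1 of 137 (RPS24A). From translocation onward, the adjusted p was 1 for each of these 10 lists. With replicate 1 alone, 6 of 20 heat shock genes were listed and that list passed (exact test, adjusted p = 0.0116). Against a background of the 551 listed genes alone, neither list kept its call with DTT (exact test, adjusted p = 0.849 for ER protein folding and 1 for glycolysis). That background leaves little room for a call, since 282 of its 551 genes were called with DTT.

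At 6 h in BYTA, PSA1, KAR2 with TAD2, PBI2, PIL1, BDF2 with YET3, YPR036W-A, and ICT1 with ERG27 ranked highest. PIL1 encodes the main component of eisosomes and YET3 an ER membrane protein. Of the 105 called genes, 100 were listed in no vegetative library, and GLK1, KAR2, PDI1, PSA1 and TAD2 were called in both states (0.262 expected, adjusted p = 5.75e-06, one-sided exact hypergeometric test, and 0.197 against the 551 listed genes alone). Genes of acetate and glyoxylate metabolism were called more often than by chance, with 5 of 17, 16.9 times expectation (exact test, adjusted p = 4.30e-04). These were the gluconeogenic genes PCK1 and FBP1 and the glyoxylate or malate enzyme genes MLS1, MDH2 and CIT2. PCK1 summits lay 543 and 526 bp upstream and MDH2 summits 386 and 387 bp upstream. Glycolysis and other strongly transcribed genes had 5 of 20, CDC19, FBA1, PDC1, CCW12 and TDH3 (14.3 times expectation, exact test, adjusted p = 5.89e-04).

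ER protein folding genes at 6 h in BYTA numbered 3 of 19, ERO1, KAR2 and PDI1, 9.05 times expectation, which missed the threshold (one-sided exact hypergeometric test, adjusted p = 0.0761). It passed when adjusted over the lists of this state alone (exact test, adjusted p = 0.0217), with each summit counted only for the nearest gene (adjusted p = 0.0468), and with scores of at least 500 (adjusted p = 0.0269). EUG1, LHS1 and SIL1 were listed in replicate 1 only, and in that replicate alone 6 of 19 were listed (exact test, adjusted p = 0.00719). Replicate 1 alone also listed 11 of 20 cytosolic heat shock genes, among them HSP104, SSA4, HSP42 and SIS1 (exact test, adjusted p = 9.45e-08), and 7 of 19 general stress genes, among them HSP12 and CTT1 (adjusted p = 8.97e-04). In both replicates, 1 heat shock gene, SSA1, and 2 general stress genes, GLK1 and YGP1, were called. Among the lists that did not pass, UPR signalling had HAC1 and glycosylation MCD4 and PMT2. Translation factors had HYP2 and amino acid synthesis LYS20. The adjusted p of the lists that did not pass, ER protein folding aside, ran from 0.439 to 1. The lists of ER-associated degradation, translocation into the ER, ER to Golgi traffic, ER shape and phospholipid synthesis, early meiosis, middle meiosis and ribosomal proteins had 0 called. Against the 551 listed genes alone, neither list that passed kept its call (exact test, adjusted p = 0.849 for acetate and glyoxylate metabolism and 1 for glycolysis).

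Of the 105 genes called at 6 h in BYTA, 77 were also called with DTT, a share of 73.3% (95% interval 63.8% to 81.5%). Chance gives 4.92 (one-sided exact hypergeometric test, adjusted p = 3.40e-82). Among the 551 listed genes alone it gives 53.7, and the excess is 1.43 times (exact test, adjusted p = 1.30e-06). Replicate 1 alone shared 198 of 340 genes and replicate 2 alone 79 of 111. HAC1, KAR2, PDI1, ERO1, ICT1, PBI2, PSA1, PCK1 and MDH2 were among the shared genes. Their summits lay a median of 15 bp apart between the states, and 76 of the 77 lay within 100 bp, KAR2 being the exception. Among genes called with DTT and listed in no library at 6 h in BYTA, 106 in all, SEC53, AXL2, YET2, CSI2 and BBP1 ranked highest. SEC53 encodes phosphomannomutase, which precedes Psa1 in GDP-mannose synthesis. In the other direction there were 26 genes, led by TAD2, FUM1 with KEL3, RPM2 and SKS1, where FUM1 encodes fumarase. TAD2 stands among them because the summit at KAR2 lay elsewhere with DTT. No list passed a test of these sets (two-sided Fisher exact tests, 0 of 16 past the threshold, 1 at an unadjusted p under 0.05), though with the few members observed no list could have passed with more under DTT (exact p = 1 with all observed members on that side). The lowest exact p was 0.0376, for acetate and glyoxylate metabolism with 0 of 106 against 2 of 26 (exact test, adjusted p = 0.601). Where genes listed in one state and not the other were taken per library and summed, so that a gene could count 2 times and the p-values are too small, 3 lists passed, with more members at 6 h in BYTA. They were acetate and glyoxylate metabolism (exact test, adjusted p = 0.00130), glycolysis (adjusted p = 0.0166) and general stress (adjusted p = 0.0241). With either replicate alone 0 lists passed.

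**Figure D3:**
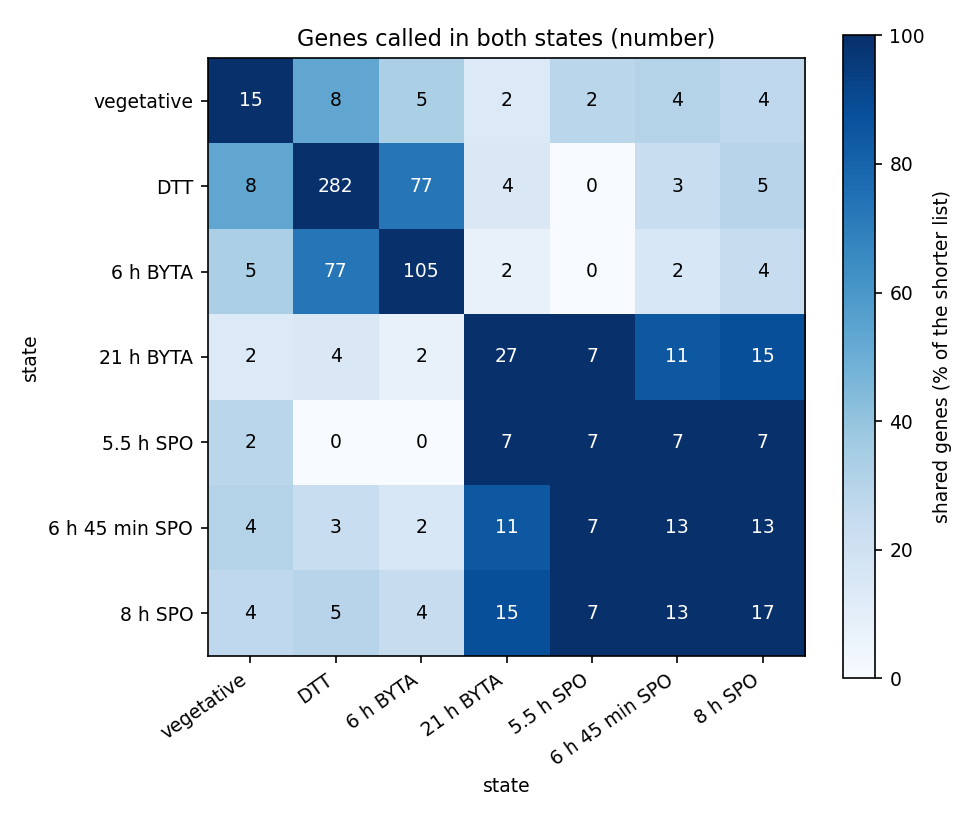
Number of genes called in each pair of states, with the number called in each state on the diagonal, and SPO standing for sporulation medium. Shading is the share of the shorter list in percent. Of 105 genes at 6 h in BYTA, 77 were called with DTT, and 15 of 17 genes at 8 h in sporulation medium were called at 21 h in BYTA.

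At 21 h in BYTA 27 genes were called, 11 of them listed in at least 1 library at 6 h in BYTA and 16 in none. YAP1802 with FMP43, NIS1 with TPM1, ARG82 with HMO1, HSH49, MBF1 with BUD7, and HAS1 ranked highest. TPM1 encodes the major tropomyosin, FMP43 a mitochondrial pyruvate carrier subunit, HMO1 a high-mobility-group protein, MBF1 a coactivator of Gcn4 and HAS1 an RNA helicase of ribosome assembly. DCP2 and MLS1, which share a promoter, were the 2 genes also called at 6 h in BYTA, an overlap that did not exceed chance (p = 0.0797, one-sided exact hypergeometric test). With replicate 1 alone, 20 genes were shared (exact test, adjusted p = 2.01e-16), so this comparison rests on replicate 2. PIL1, YPR036W-A, ICT1, ERG27 and FUM1 led the 94 genes called at 6 h and listed in no library at 21 h. NIS1, TPM1, HSH49, HAS1 and MRPS17 led the 16 genes in the other direction. No list passed a test of these sets (two-sided Fisher exact tests, 0 of 16, and 0 at an unadjusted p under 0.05), though with the few members observed no list could have passed with more at 6 h (exact p = 1 with all observed members on that side). MRPS17 and GCV2 were shared with vegetative cells (exact test, adjusted p = 0.00196, and 0.197 against the 551 listed genes alone), and with replicate 1 alone 9 genes were (adjusted p = 7.65e-15).

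ARG82, HMO1, DCP2 and MLS1 were called both with DTT and at 21 h in BYTA, 14.8% of 27 genes (95% interval 4.19% to 33.7%, adjusted p = 0.0442, one-sided exact hypergeometric test). This call ended when a summit counted only for the nearest gene (exact test, adjusted p = 0.573), and against the 551 listed genes alone the overlap lay below expectation. With replicate 1 alone 18 of 36 genes were shared (exact test, adjusted p = 5.31e-13). KAR2 and PDI1 were each listed in replicate 1 at 21 h and not in replicate 2. No list passed at 21 h in BYTA (one-sided exact hypergeometric tests, 0 of 16, and 0 at an unadjusted p under 0.05). MDJ1 of the heat shock list and MLS1 of the acetate list were the called members at this time. With 27 called genes, at most 0.614 members of any list were expected, so these tests had little power. Whether lists differ between DTT and 21 h in BYTA could not be judged. With 269 genes against 17, ER protein folding had 7 against 0 members at p = 1 (two-sided Fisher exact test), and with the few members observed no list could have passed with more under DTT.

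In sporulation medium the genes listed in both libraries of a time were all called again at the later times, which did not hold within each replicate. At 5.5 h they were TPM1 with NIS1, MRPS17 with GCV2, MBF1 with BUD7, and HSH49, and these 7 were called again at 6 h 45 min and at 8 h. At 6 h 45 min KAR2 with TAD2, ARG82 with HMO1, and YAP1802 with FMP43 were called as well, and these 13 were called again at 8 h. At 8 h CPR1 with RPA14 and DCP2 with MLS1 completed the 17 genes. MRPS17 encodes a mitochondrial ribosomal protein, GCV2 a glycine decarboxylase subunit, CPR1 a cyclophilin and DCP2 the mRNA decapping enzyme. Each overlap exceeded chance (one-sided exact hypergeometric tests, largest adjusted p = 4.57e-19). KAR2 and TAD2 were the genes called at 6 h 45 min and listed in neither library at 5.5 h, and this was also so at 8 h. The other genes called only at later times were already listed in replicate 2 at 5.5 h, where replicate 1 listed 7 genes. Replicate 2 alone listed 29, 24 and 29 genes at the 3 times, with 22 shared between the first 2 times, 23 between the last 2 and 25 between the first and last. Replicate 1 alone listed 7, 16 and 19 genes, with 7, 13 and 7 shared.

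TPM1 and NIS1 shared the best-ranked summit in both libraries at 6 h 45 min and at 8 h. The TPM1 window spans positions 482298 to 482897 of chromosome XIV, and the summits lay 196 to 214 bp upstream of TPM1 in the 6 sporulation libraries. Between vegetative cells and sporulation medium, MRPS17 and GCV2 were shared at 5.5 h (adjusted p = 1.45e-04), and these with KAR2 and TAD2 at 6 h 45 min (adjusted p = 1.06e-07) and 8 h (adjusted p = 1.75e-07, one-sided exact hypergeometric tests). PSA1, DFR1, FSF1, YTM1 and UTR5 were called in vegetative cells and listed in no library at 6 h 45 min or 8 h. YAP1802, FMP43, HSH49, MBF1 and BUD7 led the genes at 8 h that were listed in no vegetative library. MRPS17 with GCV2 and KAR2 with TAD2 each share a summit, so these p-values count a site more than once. With each summit counted only for the nearest gene, 1 gene was shared at each time (exact test, adjusted p = 0.0191, 0.0191 and 0.0196). With scores of at least 500, 0 genes were shared between vegetative cells and 5.5 h, and with replicate 1 alone 4 were shared at 5.5 h and 8 at 8 h.

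Genes called both with DTT and in sporulation medium were 0 of 7 at 5.5 h (adjusted p = 1), ARG82, HMO1 and KAR2 at 6 h 45 min (adjusted p = 0.0342), and these with DCP2 and MLS1 at 8 h (adjusted p = 0.00211, one-sided exact hypergeometric tests). The share at 8 h was 29.4% of 17 genes (95% interval 10.3% to 56.0%). Both calls ended when a summit counted only for the nearest gene (exact test, adjusted p = 0.392 and 0.106), and against the 551 listed genes alone both overlaps lay below expectation. With replicate 1 alone, more genes were shared with DTT, 4 of 7 at 5.5 h (exact test, adjusted p = 3.81e-04), 9 of 16 at 6 h 45 min (adjusted p = 8.71e-08) and 13 of 19 at 8 h (adjusted p = 3.30e-12). MRPS17, GCV2, YAP1802, FMP43 and HSH49 were called at 8 h and listed in neither DTT library. No list passed in sporulation medium (one-sided exact hypergeometric tests, 0 of 16 at each time), with 0, 1 and 1 lists at an unadjusted p under 0.05 at 5.5 h, 6 h 45 min and 8 h. At most 0.387 members of any list were expected at any of these times, so these tests had little power. KAR2 was the called member of the ER folding list at 6 h 45 min (exact test, adjusted p = 0.439) and at 8 h (adjusted p = 0.451), and PDI1 was listed in 1 library at 8 h. With replicate 1 alone, where KAR2 and PDI1 were both listed at 8 h, that list passed (exact test, adjusted p = 0.0194). Whether lists differ between DTT and 8 h in sporulation medium could not be judged either, with 275 genes against 6 and 0 members of any list among the 6 (two-sided Fisher exact tests, p = 1 for each list).

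**Figure D4:**
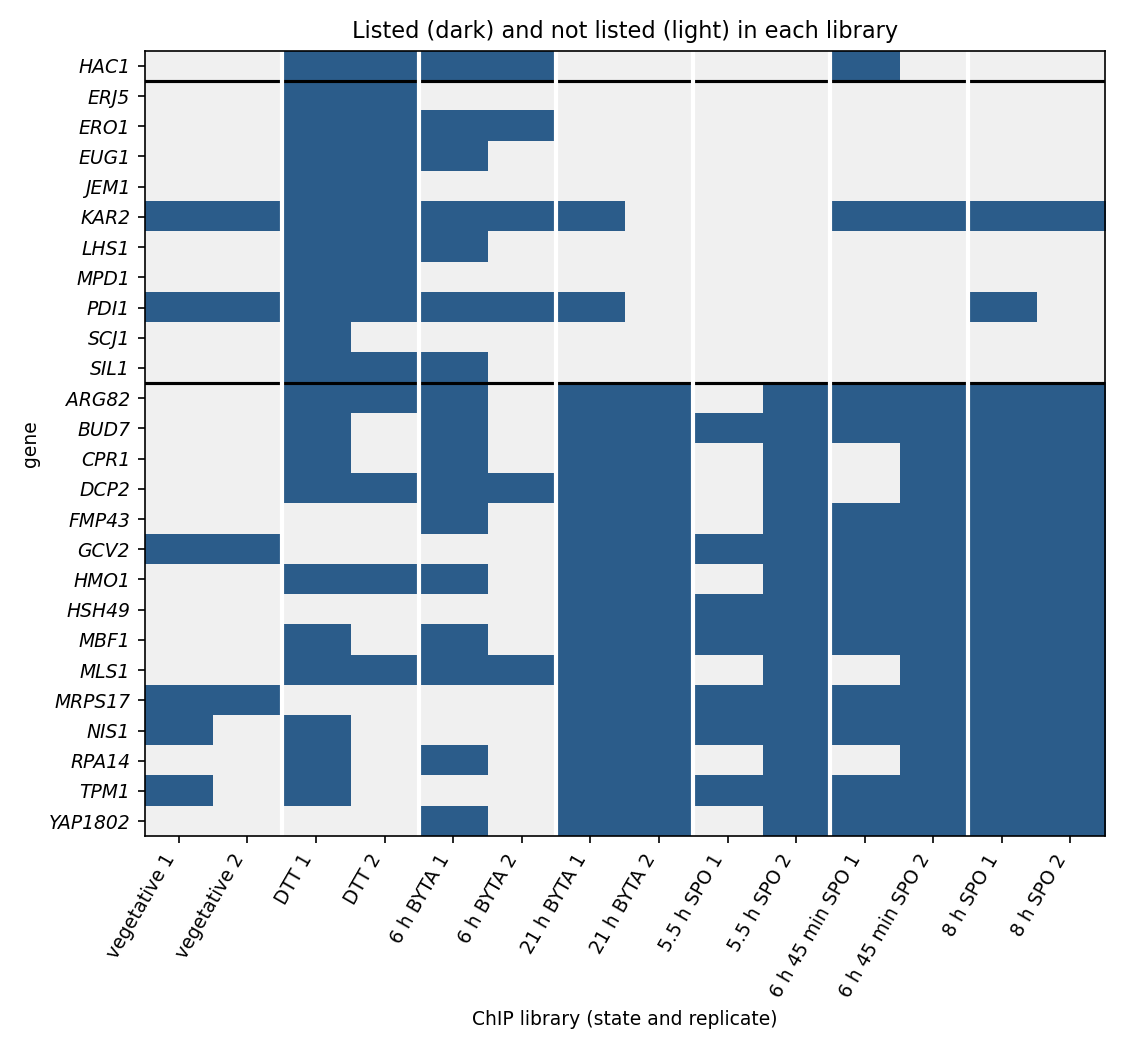
Presence of HAC1, of ER protein folding genes listed with DTT, and of the 15 genes called both at 21 h in BYTA and at 8 h in sporulation medium (rows) in 14 ChIP libraries (columns), with SPO standing for sporulation medium. Dark cells are listed genes. The folding genes other than KAR2 and PDI1 were listed in libraries of DTT and of 6 h in BYTA alone.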

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

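The share tests and the tests of explanations in this part were chosen after the overlaps had been seen. The share of called genes that were also called with DTT differed between time points. It was 73.3% of 105 genes at 6 h in BYTA and 14.8% of 27 genes at 21 h (two-sided Fisher exact test, adjusted p = 1.10e-07 over 3 comparisons). It was 29.4% of 17 genes at 8 h in sporulation medium, which also differed from 6 h in BYTA (exact test, adjusted p = 0.00103), while 21 h in BYTA and 8 h in sporulation medium did not pass such a test (adjusted p = 0.275). Both differences rest on replicate 2. With genes called in either replicate they fell to 17.4 and 16.7 points and no longer passed (exact test, adjusted p = 0.0826 and 0.132). With replicate 1 alone the shares were 58.2% at 6 h in BYTA, 50% at 21 h and 68.4% at 8 h in sporulation medium (exact test, adjusted p = 0.476 for both differences). With replicate 2 alone they were 71.2%, 13.5% and 17.2% (exact test, adjusted p = 3.05e-09 and 3.05e-07). Replicate 1 of the DTT state listed TPM1 with NIS1, MBF1 with BUD7 and CPR1 with RPA14, which recur at 21 h and in sporulation, and replicate 2 did not. Vegetative cells and 6 h in BYTA showed the same split. With 21 h in BYTA, vegetative cells shared 9 genes in replicate 1 and 2 in replicate 2, and 6 h in BYTA shared 20 and 2. With 8 h in sporulation medium, vegetative cells shared 8 and 4 genes, and 6 h in BYTA 14 and 4. The lists at 6 h in BYTA also differed in length, with 340 and 111 genes. Contrasts with 21 h in BYTA and 8 h therefore depend on the replicate number.

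The overlap between 6 h in BYTA and DTT was itself present in each replicate. One explanation is that the same positions are bound in both states, and the summits of the 77 shared genes lay a median of 15 bp apart, KAR2 being the single gene beyond 100 bp. Another is that strong transcription gives peaks in any ChIP. Such peaks could coincide too, so the distance between summits does not tell these explanations apart. Glycolytic and other strongly transcribed genes were called more often than chance with DTT and at 6 h in BYTA, whereas ribosomal protein genes, also strongly transcribed during growth, were called less often with DTT (1 of 137, one-sided exact lower-tail hypergeometric test, p = 0.0102). That low count depends on calling in both replicates, as RPL22A, RPL6A and RPS4A were each listed in 1 DTT library. At 6 h in BYTA 0 ribosomal protein genes were called, and 7 were listed in 1 library. Of the 20 glycolytic and other strongly transcribed genes, 0 were listed in either vegetative library. Those lists were short, and an unlisted gene is not shown to be unbound. No expression was measured here, also not under DTT or in BYTA, so these lists do not decide the question. Strong transcription may account for part of the overlap and cannot be told apart from regulated binding.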

How the results depend on the processing

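Chosen after the data were seen were scores filtered at 500, counting a summit only for the nearest gene, list differences on genes listed per library, and the listed-gene background for overlaps other than those of DTT with BYTA and sporulation. The 282 genes called with DTT stayed within 1.5 times under each alternative. The overlap of DTT with 6 h in BYTA, those of vegetative cells with 6 h 45 min and 8 h in sporulation medium, those among sporulation times and those of 21 h in BYTA with sporulation kept their direction and side of the threshold in every alternative that was run. For vegetative cells with 6 h 45 min and with 8 h, counting only the nearest gene left 1 shared gene each. Calling genes in either replicate gave 25 vegetative genes, 346 at 6 h in BYTA, 46 at 21 h, and 29, 27 and 31 at 5.5 h, 6 h 45 min and 8 h in sporulation medium. It gave 21 genes shared between 6 h and 21 h in BYTA, 10 between DTT and 5.5 h, and 11 between 6 h in BYTA and 5.5 h, all then past the threshold. It gave 5 lists past the threshold at 6 h in BYTA and 1 at 8 h in sporulation medium. Without replicate 1 or without replicate 2, vegetative genes ranged from 17 to 23, those at 6 h in BYTA from 111 to 340, and those in sporulation medium from 7 to 29, 16 to 24 and 19 to 29. Genes shared between 6 h and 21 h in BYTA ranged from 2 to 20, and those of DTT and 5.5 h were 4 either way. Lists ranged from 2 to 5 at 6 h in BYTA and from 0 to 1 at 8 h in sporulation medium. The difference in share with DTT between 6 h in BYTA and 8 h in sporulation medium, 43.9 points, ranged from -10.2 to 53.9. The longer lists follow from the looser rule by construction.

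Counting only the nearest gene left 16 genes at 21 h in BYTA and 4, 7 and 9 in sporulation medium. It left 1 gene shared by DTT and 21 h in BYTA, 1 and 2 by DTT and 6 h 45 min and 8 h, 1 by 6 h in BYTA and 6 h 45 min, and 0 lists in vegetative cells. Under this rule genes that share a summit count once, and the same site can go to different genes in different libraries. In vegetative replicate 1 the KAR2 summit counted for TAD2, 158 bp upstream of it against 168 bp for KAR2. In replicate 1 at 6 h 45 min it counted for KAR2, at 156 against 170 bp. Scores of at least 500 left 65 genes at 6 h in BYTA, 2 at 5.5 h and 4 at 6 h 45 min. They left 0 genes shared by vegetative cells and 5.5 h, 0 by DTT and 6 h 45 min, 0 by 6 h in BYTA and 6 h 45 min, and 0 vegetative lists. The 2 genes shared by 6 h and 21 h in BYTA then passed. Against the 551 listed genes alone, the overlaps of DTT with 21 h in BYTA (4), 6 h 45 min (3) and 8 h (5) fell below expectation, as did that of 6 h in BYTA with 6 h 45 min (2). Those of vegetative cells with DTT (8), 6 h in BYTA (5) and 21 h in BYTA (2), and that of 6 h in BYTA with 8 h (4), no longer passed. With this background 0 lists passed in vegetative cells, with DTT or at 6 h in BYTA. Most of its genes were listed with DTT or at 6 h in BYTA, so lists and overlaps of these states had little room to pass.

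An exact stratified test with the replicate number as a block took genes listed per library, other genes than those called in both. A gene listed in both libraries of a state entered both blocks, so the p-values of this test are too small. It found 3 lists that differ between DTT and 6 h in BYTA, against 0 on called genes, namely acetate and glyoxylate metabolism (exact test, adjusted p = 0.00244) and, at adjusted p = 0.0375 each, general stress and glycolysis. Summing the same genes with no block, where a gene listed in both libraries counts 2 times, also gave 3, and each replicate alone gave 0. No other list difference changed. Same-numbered libraries of different states correlated between -0.0655 and 0.624 (median 0.00929) in their deviations, with the highest values, 0.423 to 0.624, among the 3 sporulation times, and the labels do not say that numbers pair libraries. The sporulation libraries may be 2 time courses, and overlaps among these times would then not be between independent samples. Not run were a cutoff on q or fold, which the tables do not carry, the overlap of peak intervals, the motif alternatives and the alternatives for peak positions. A limit of peaks to the promoter removes nothing here. Read depth is unknown, so what depth limits could not be judged.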

Other observations

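The gene groups, comparisons and tests in this part were chosen after the data had been seen. The groups were drawn up after the called genes had been seen, so their p-values describe them and are not tests of over-representation. Of 25 cell wall protein genes, 11 were called with DTT, among them CCW12, CIS3, CWP1, GAS1, PIR1 and SED1 (9.39 times expectation, one-sided exact hypergeometric test, adjusted p = 3.89e-08 over 8 tests). At 6 h in BYTA, 5 of them were called, CCW12, CWP1, PRY1, SED1 and ZEO1 (exact test, adjusted p = 1.57e-04). Of 20 genes for drug and polyamine export, the same 6 were called in both states, the transporter genes PDR5, PDR15, SNQ2, TPO1 and TPO4 and the lipid transfer gene PDR16 (exact test, adjusted p = 4.45e-04 with DTT and 3.10e-06 at 6 h in BYTA). Of 25 iron and copper uptake genes, CTR1, CTR3, FET3, FRE1, FRE4 and FTR1 were called with DTT (exact test, adjusted p = 0.00133), and CTR1, FRE4 and FTR1 at 6 h in BYTA (adjusted p = 0.0120). Ergosterol synthesis had 3 of 22 with DTT, ERG3, ERG25 and ERG27, which missed the threshold (exact test, adjusted p = 0.0927). Against the 551 listed genes alone, cell wall proteins with DTT (exact test, adjusted p = 0.0148) and drug and polyamine export at 6 h in BYTA (adjusted p = 0.00680) stayed past the threshold, and the other 6 did not (adjusted p = 0.156 to 0.654).

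Most genes called in sporulation medium were also called at 21 h in BYTA, before sporulation. All 7 genes called at 5.5 h, 11 of 13 at 6 h 45 min and 15 of 17 at 8 h were also called at 21 h in BYTA (one-sided exact hypergeometric tests, adjusted p = 1.57e-17, 1.62e-25 and 1.90e-35). KAR2 and TAD2 were the exceptions, and KAR2 was listed in 1 library at 21 h. Between 6 h in BYTA and sporulation medium, 0 genes were shared at 5.5 h, KAR2 and TAD2 at 6 h 45 min (exact test, adjusted p = 0.0311), and these with DCP2 and MLS1 at 8 h (adjusted p = 5.24e-04). KAR2 and TAD2 share a summit, so the overlap at 6 h 45 min rests on 1 site. It did not pass with only the nearest gene counted (exact test, adjusted p = 0.139), and scores of at least 500 left 0 genes. The overlap at 8 h passed under both rules (exact test, adjusted p = 0.0190 and 0.0249). Against the 551 listed genes alone neither of these 2 overlaps passed (exact test, adjusted p = 1), and with replicate 1 alone 11 of 16 and 14 of 19 genes were shared. BUD7, GCV2, HSH49, MBF1, MRPS17, NIS1 and TPM1 were listed in all 8 libraries of these 4 late states. HSH49 was listed in no other library. The other genes were each listed in 10 libraries, MRPS17 and GCV2 in both vegetative ones.

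The recurrence of these promoters may reflect a preference for promoters shared by divergent genes. Of the summits listed in both replicates, 88.9% of 9 at 8 h in sporulation medium lay in 2 windows, against 24.5% of 229 with DTT (two-sided Fisher exact test, p = 1.38e-04). The share over all promoters was not worked out. The test therefore compares these states with each other and does not show why the same sites recur. Another candidate explanation is a set of sites recovered in every ChIP and hidden where other peaks are strong. Where the 15 genes shared by 21 h in BYTA and 8 h were listed with DTT or at 6 h in BYTA, a median of 55.1% of that library's summits had higher scores, with a range from 3.38% to 99.0%. In 34 of 60 pairs of a gene and a library they were not listed, and unlisted peaks have no value here, so site preference and background sites cannot be told apart.

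Replicate 2 at 6 h in BYTA listed fewer genes than replicate 1 by a ratio of 3.06. The highest peak numbers among the listed summits, 1783 and 1361, differed by a ratio of 1.31. They are lower bounds of the number of called peaks, so whether fewer called peaks account for the shorter list could not be judged. Weaker enrichment or a stricter effective selection in replicate 2 could not be judged from the scores. Genes listed in both outscored genes listed in replicate 1 alone with a probability of 0.959, but over the 7 states this probability ran from 0.873 to 0.974, and it was 0.970 at 21 h in BYTA, where the lists were about equally long. Whether the cultures differed was not tested, and replicate 1 alone carries most of the heat shock genes.

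The KAR2 summit lay a mean of 288 bp farther upstream in the 2 DTT libraries than in the 9 other libraries that listed it and was not tested. The positions of the 2 DTT summits also differed from each other, at 391512 and 391632.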
